A study of Homo sapiens with 12 samples.

How the data were processed

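RNA of NCI-H69 cells was sequenced in 12 libraries, which are m6A immunoprecipitates and inputs of 3 DMSO and 3 FB23-2 samples. Per the labels' protocols, polyadenylated RNA was isolated with oligo(dT) beads, fragmented and made into indexed libraries by adapter ligation and PCR. The submitters' processing notes name FastQC, Trimmomatic, STAR, featureCounts and DESeq2 and the build GRCh38 (hg38), with no versions and no roles. Peak names in the files start with MACS, a peak caller, whose version and settings are not given in the sources used here. The authors deposited 1 list per IP and input pair, so that replicates were not pooled before peaks were called.

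Per the file headers, each site has a chromosome, a start and an end, a transcript and a gene. The deposited significance of a site is a score, minus 10 times the log10 of the caller's p, of at least 50 in every list, which is what a p threshold of 1e-05 gives, and with a ceiling shared by many sites. The deposited fold enrichment is the caller's ratio of the IP over its background. The deposited false discovery rate is in percent. Its median was 99.1 to 100% in every list, so that it was not used as a filter. Only 3 sites, all in DMSO replicate 2, had a rate of 5% or less. None of these values is normalised between lists, and a site's fold was therefore not compared between lists. Starts matched gene starts of the reference table after adding 1 (1054 of the distinct intervals, against 132 as given), so 1 was added to every printed start. Ends matched gene ends as given for 1112 intervals. Of the 11495 sites found in all 6 lists, 7202 (62.7%) had identical borders in every list. Borders may therefore follow the annotation in part, and lengths and numbers of sites may depend on it.

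Peak numbers ran up to 27543 to 35547 per list, and the lists hold 58.4 to 63.1% of them. Numbers follow genome order, so a missing number between listed neighbours marks a peak that was called but is outside these lists. Gene names were updated by gene ID to the symbols of the GRCh38.p14 reference table. Of 10112 names, 9872 matched, 335 of these had a newer symbol, 193 others were already current, and 47 were kept as given.

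Sites of the 6 lists were merged where they overlapped by at least 1 base. The files give no strand, so the planned merging by strand was done without it. A site was group-specific when listed in 3 of 3 lists of one treatment and 0 of 3 of the other, and the count was repeated for all 10 splits of the lists. Numbers per list were compared by two-sided exact permutation tests, and 17 gene lists by Fisher's exact test against genes with a site in at least 3 lists, with Benjamini-Hochberg adjustment over lists and directions and a threshold of 0.05. The test within classes was an exact conditional test over 6 classes of genes with at least 1, 2, 3, 4, 6 or 10 sites. Pathway and Gene Ontology terms of 10 to 500 genes, as annotated in the files, were tested by one-sided Fisher's exact tests. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. In lists simulated from the 27799 real sites with 200 planted group-specific sites, all 200 were recovered with the right direction, as the rule makes nearly certain. That split gave 448 sites in total, so others were called that had not been planted, and the 9 other splits gave up to 272. In 1000 tests of random gene lists over 8615 genes, 1.7% passed 0.05 in the test within classes. Of 50 planted lists with 6 hits among 18 members, 50 were found, which was nearly certain because each was built to hold these hits.

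The groups, the gene lists, the tests and most alternatives were fixed before the data were examined. So was the rule for named genes. It took the 10 sites of each direction with the highest mean rank of significance within their lists (1 per gene), 12 genes of m6A enzymes and small cell lung cancer, up to 4 members with a group-specific site per gene list, and the 5 genes each way whose number of sites differed most without overlap between treatments. Other members of a list that passed its test were named as well, and some genes that the rule takes are not reported here. The alternatives were the best 50% of each list, equal numbers of top-ranked sites, each list left out, 50% reciprocal overlap, genes or merged regions as units, and the replicate number as a block. The planned fit of read counts per site, the input expression, the position in transcripts and the sequence motif were not run, since the lists hold no counts and no position within the transcript, and no genome sequence was used here.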

Results

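The study profiled N6-methyladenosine (m6A), a methyl mark on the adenosines of messenger RNA, in NCI-H69, an established neuroendocrine cell line of human small cell lung cancer. Cells received either the solvent DMSO or FB23-2, an inhibitor of FTO, an enzyme that removes m6A. Polyadenylated RNA was immunoprecipitated for m6A (IP) and sequenced beside its input. The 12 libraries form 4 groups of 3, which are DMSO IP, DMSO input, FB23-2 IP and FB23-2 input. The values analysed are 6 lists of m6A sites, each called from 1 IP library and its own input and limited to sites assigned to messenger RNAs. Read depth is unknown, because the lists hold no read counts. Nothing in the labels says whether the replicates were separate cultures, so the spread between lists may be technical.

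The first comparison asked whether inhibiting the demethylase changed how many sites were called. The DMSO lists held 17939, 18872 and 20766 sites and the FB23-2 lists 18720, 19415 and 17368. The means were 19192 ± 1440 sites with DMSO and 18501 ± 1041 with FB23-2 (SD, n = 3 each). Genes with at least 1 site numbered 8498 ± 337 with DMSO and 8323 ± 169 with FB23-2. Neither difference exceeded the spread between lists (two-sided exact permutation p = 0.5 for sites and p = 0.6 for genes, where 0.1 is the smallest p that 3 against 3 allow). Without DMSO replicate 3, the longest list, FB23-2 had 95.5 more sites per list on average. Within the lists, the median fold enrichment given by the authors' peak caller ran from 8.04 to 12.4. The caller's fold and significance are the authors' own values and serve here to describe and rank sites within a list. Medians of the caller's false discovery rate were 99.1 to 100% per list. Neither motif nor position was examined, so the listed sites were not checked independently as m6A.

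Merging overlapping sites gave 27799 sites in 10112 genes, of which 11495 (41.4%) were in all 6 lists, in 6416 genes, and 5175 (18.6%) in a single list. INSM1, a neuroendocrine transcription factor, had 1 site in every list, with folds of 12.7 to 23.6. BCL2, an inhibitor of apoptosis, had 2 sites in every list, with folds of 13.2 to 30.0 at the stronger of them. MYC had 2 sites in every list and a further site in FB23-2 replicates 2 and 3. FTO itself had 1 site in every list (chromosome 16 from 53825864 to 53826491, folds of 5.54 to 11.9) and a further site in FB23-2 replicate 3, and ALKBH5, the other m6A demethylase, had 3 in every list. YTHDF2, a reader protein of m6A, had 1. METTL14, a subunit of the m6A writer complex, had 1 site in 3 DMSO and 2 FB23-2 lists, another in 2 DMSO and 3 FB23-2 lists, and a further site in FB23-2 replicate 1. No site of METTL3, MYCL, MYCN or NEUROD1 was listed. Lists of the same treatment resembled each other more than lists of different treatments. The Jaccard index, the share of the sites of a pair of lists that both hold, averaged 0.705 ± 0.0119 (SD) over the 6 pairs within a treatment and 0.652 ± 0.0162 over the 9 pairs between treatments. The difference of 0.0524 was the highest of the 10 splits of the lists (exact permutation p = 0.1, the smallest possible), and the highest of the other splits was 0.0025.

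The main comparison asked which sites were present with 1 treatment and absent with the other. A total of 668 sites in 574 genes were listed in 3 of 3 DMSO lists and 0 of 3 FB23-2 lists (DMSO-specific), and 446 sites in 388 genes showed the opposite pattern (FB23-2-specific). Counted the same way, the 9 other splits of the 6 lists gave 131 to 279 sites against 1114 for the real split. A test per site cannot pass 0.05 with 3 lists against 3, and a site that is not listed is not shown to be unmethylated. For 379 of the 1114 sites, a peak number was missing at the site's place in all 3 lists that lacked it, so that a peak called there but outside the mRNA lists is possible. For 290 more, this was so in 1 or 2 of those lists. The surplus of DMSO-specific over FB23-2-specific sites was 222, but it was 88 when every list was limited to its 17368 top-ranked sites and 10 without FB23-2 replicate 3. Group-specific sites were weaker than shared ones, and 81.7% of them had a mean rank in the weaker 50% of their lists, against 31.5% of the sites in all 6 lists. Their median significance score (minus 10 times the log10 of the caller's p) was 144 against 603 for sites in all 6 lists. For 608 of the 1114 sites (54.6%), the same gene had another site in all 3 lists of the other treatment. Counted by genes, 209 had a site in every DMSO list and in no FB23-2 list, and 118 the reverse, against at most 55 in total in the other splits.

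**Figure D1:**
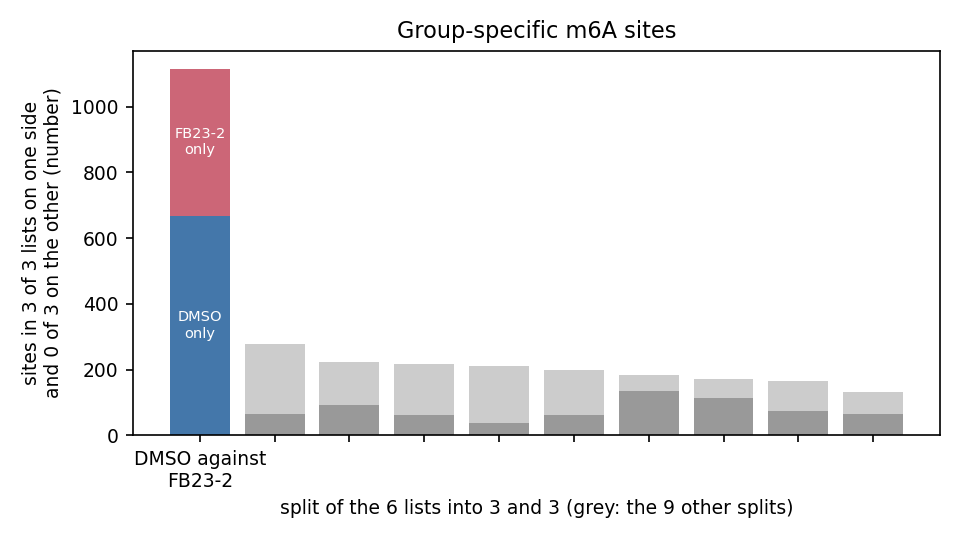
The vertical axis counts the sites found in 3 of 3 lists on one side and 0 of 3 on the other, and each bar is 1 of the 10 splits of the 6 lists, with the sides stacked. The DMSO against FB23-2 split, in colour, holds 668 DMSO-specific and 446 FB23-2-specific sites, and the highest of the 9 other splits, in grey, holds 279.

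The strongest DMSO-specific sites, ranked by the caller's significance, lay in EIF4A3, MUC5AC, ZFTA (C11orf95 in the lists), MUC5B, DEK, DHDDS, MID1IP1, RABL6, SFPQ and PKD1. The site of EIF4A3, a helicase of the exon junction complex, spanned chromosome 17 from 80146793 to 80147183 with folds of 64.0 to 93.6. The site of DHDDS, an enzyme of dolichol synthesis, spanned chromosome 1 from 26468892 to 26471294 with folds of 39.2 to 45.8. In SFPQ, which encodes a splicing factor, a site of 122 bases on chromosome 1 (35187001 to 35187122) had folds of 9.06 to 12.5. Of these genes, MUC5AC and MUC5B had no site in any FB23-2 list, and the other 8 had another site in all of them. The site of PKD1, the gene of polycystin-1, had folds of 30.9 to 40.5. At the sites of EIF4A3, RABL6 and PKD1, a peak number was missing in all 3 FB23-2 lists, so an unlisted peak may lie there.

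The strongest FB23-2-specific sites lay in DEK, MYH9, PATZ1, MID1IP1, PCNX3, AMOTL1, ATP11A, MRPL23, CACNA1A and POLR2J, and all 10 genes had another site in every DMSO list. At 7 of these sites, those of PATZ1, PCNX3, AMOTL1, ATP11A, MRPL23, CACNA1A and POLR2J, a peak number was missing in all 3 DMSO lists, so an unlisted peak may lie there. The site of CACNA1A, a neuronal calcium channel subunit, spanned chromosome 19 from 13208756 to 13209009 with folds of 40.0 to 58.6. The site of MYH9, a non-muscle myosin heavy chain, spanned 129 bases of chromosome 22 (36286718 to 36286846) with folds of 26.2 to 39.9. PATZ1, a zinc finger transcription factor, had a site of 1901 bases with folds of 25.9 to 35.1. In DEK, which encodes a chromatin protein, the DMSO-specific site (chromosome 6 from 18264385 to 18264823) and the FB23-2-specific site (18263843 to 18264208) lay next to each other. The same held for MID1IP1 on chromosome X, with the DMSO-specific site at 38802544 to 38804413 and the FB23-2-specific site at 38804683 to 38806509. In both genes, the neighbouring sites were assigned to different transcripts, and whether they are separate sites was not tested. A total of 25 genes carried specific sites of both directions, against 25.9 for independent sets of this size. That expected number takes no account of distance, and in 9 of the 25 genes sites of opposite direction lay within 1000 bases of each other.

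FB23-2-specific sites were more frequent in genes of the integrated stress response and the unfolded protein response, programmes that cells switch on when amino acids run short or proteins misfold, than in other genes. Of 18 members with a site in at least 3 lists, 6 (33.3%) had an FB23-2-specific site, against 4.50% of all 8615 such genes, and none had a DMSO-specific one (Fisher's exact test, two-sided, adjusted p = 0.0032 over 34 tests). These were ATF3, a stress-induced transcription factor, TRIB3, a pseudokinase, CHAC1, an enzyme that breaks down glutathione, SESN2, a leucine-sensing sestrin, SLC3A2, the heavy chain of amino acid transporters, and VLDLR, a lipoprotein receptor. SESN2 had 5.33 ± 0.577 sites per FB23-2 list and 0.333 ± 0.577 per DMSO list (SD, n = 3 each). TRIB3 had 4 sites in every FB23-2 list and 1 in every DMSO list, ATF3 had 3 against 1, and CHAC1 had 2 against 1. The strongest of these sites were at ATF3 (chromosome 1 from 212608628 to 212608930, folds of 13.6 to 16.3), CHAC1 (chromosome 15 from 40953152 to 40953814, folds of 8.74 to 12.1) and TRIB3 (chromosome 20 from 380639 to 381169, folds of 9.16 to 17.1). Members of the same list without a group-specific site included ATF4, the central transcription factor of the response, with 1 site in every list, and DNAJB9, a chaperone of the endoplasmic reticulum, with 2. Over all 18 members, the mean number of sites was higher with FB23-2 for 8, equal for 6 and lower for 4. The 4 were PPP1R15A, a regulatory subunit of a phosphatase (1.33 ± 0.577 with FB23-2 against 2.67 ± 0.577 with DMSO), PSAT1, HSPA5 and XBP1. Gene list tests count genes as independent, which members of 1 programme may not be, so their p may be too low. They do not measure the spread between lists.

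**Figure D2:**
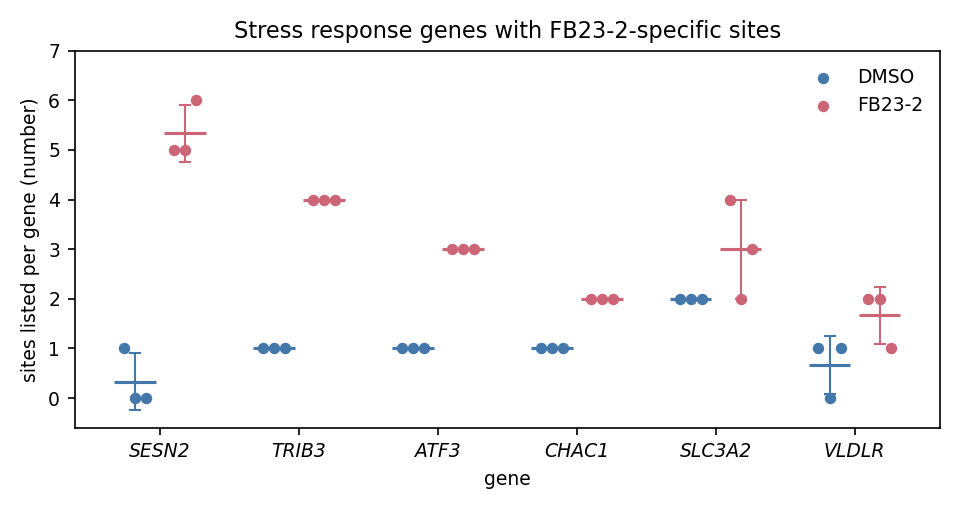
The vertical axis is the number of sites listed for each of the 6 stress response genes with an FB23-2-specific site, with 1 point per list, DMSO in blue and FB23-2 in red, and lines and bars for mean and SD (n = 3 each). SESN2, TRIB3, ATF3 and CHAC1 had more sites in each FB23-2 list than in any DMSO list, and SLC3A2 and VLDLR overlapped between treatments.

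Axon guidance genes, which steer growing nerve fibres, had DMSO-specific sites in 6 of 23 members (26.1%, against 6.66% of all genes tested; Fisher's exact test, adjusted p = 0.0367) and FB23-2-specific sites in none. They were SEMA3A, SEMA4D, PLXNA2, EPHB2, SLIT1 and EPHA7. The site of SEMA3A, a secreted guidance cue, lay on chromosome 7 from 84194475 to 84194901 with folds of 7.98 to 13.6, and a peak number was missing there in 2 FB23-2 lists. Of the ZNF zinc finger genes, fewer members than of other genes had a DMSO-specific site (10 of 357, 2.80%, Fisher's exact test, adjusted p = 0.026), with examples in ZNF827, ZNF791 and ZNF618. With sites as units, this call was lost (12 of 596 sites against 20.5 expected, Fisher's exact test, adjusted p = 0.352). FB23-2-specific sites were also in 10 of the 357 (2.80%, against 4.50% of all genes; Fisher's exact test, adjusted p = 1). Both calls were lost in an exact test within classes of genes with like numbers of sites (adjusted p = 0.288 for axon guidance, with 6 genes against 2.39 expected, and p = 0.174 for ZNF genes, with 10 against 20.7), where the expected numbers without classes were 1.53 and 23.8, while the call for the stress response genes was kept (exact test, adjusted p = 0.0022).

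The other 14 lists did not pass the test in either direction (Fisher's exact test, every adjusted p = 1). Of the m6A machinery, 16 of 28 members had a site in all lists, and only YTHDF3, a reader protein, had a group-specific site (DMSO-specific, chromosome 8 from 63168553 to 63168901, folds of 27.2 to 29.7). Neuroendocrine genes had sites in all lists for 27 of 35 members and group-specific sites for none. The described FTO targets of other cell types and the glycolysis genes had no group-specific site either, with 9 members tested in each list. Only 0.60 DMSO-specific and 0.41 FB23-2-specific genes were expected in each, so finding none says little about these genes. Apoptosis genes and p53 targets had FB23-2-specific sites in BBC3 and SESN2 and a DMSO-specific site in BAX, where BBC3 and BAX promote apoptosis. A peak number was missing in all 3 lists that lacked the site for YTHDF3, BBC3, BAX, EZH1 and RPS24. Single members had group-specific sites in other lists. Among them were MXD1 of the MYC network, E2F8 of the cell cycle, EZH1 of the chromatin modifiers, ATF3 of the immediate early genes and RPS24 of the ribosomal protein genes with FB23-2-specific sites, and NOTCH1 of the Notch and YAP genes, MCM3 of the cell cycle and IMPDH1 of nucleotide synthesis with DMSO-specific ones. Of 26 markers of blood, stroma, endothelium and other cell types, 2 had a site in any list and none in all lists.

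**Figure D3:**
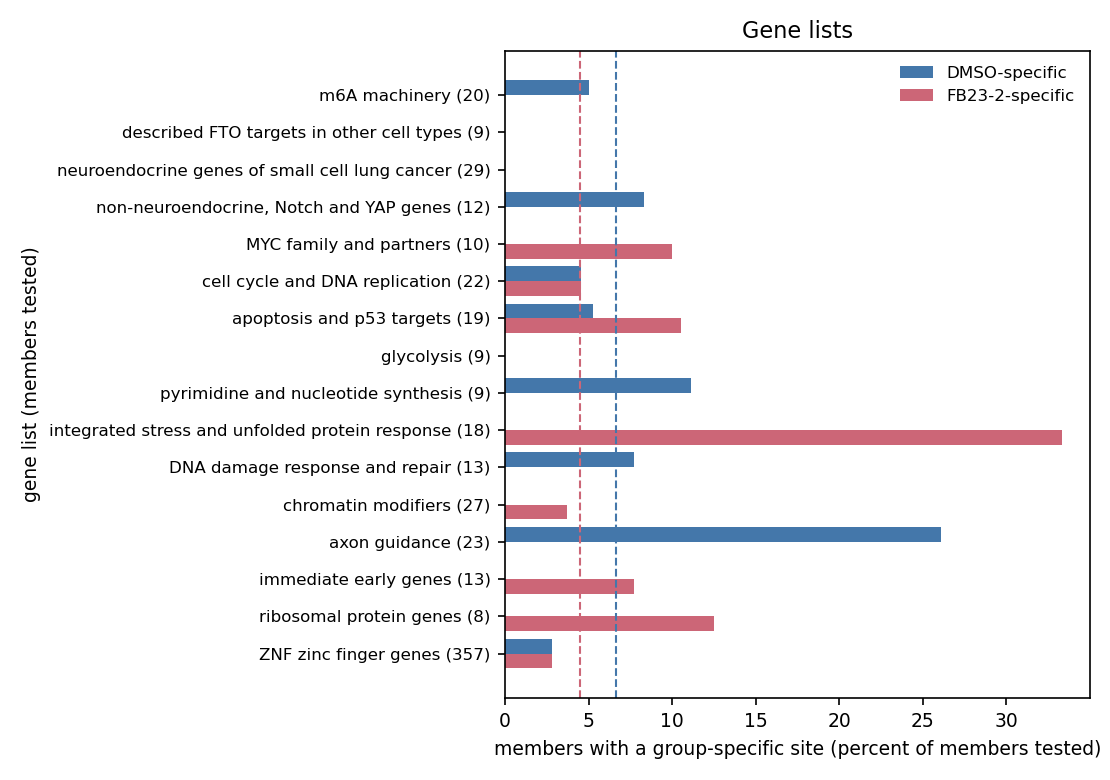
Bars give the percent of each list's members with a DMSO-specific (blue) or FB23-2-specific (red) site, over the members with a site in at least 3 lists (number in brackets), and dashed lines give the percent over all 8615 genes. The stress response list reached 33.3% for FB23-2-specific and the axon guidance list 26.1% for DMSO-specific sites.

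Of the secreted gel-forming mucin genes on the short arm of chromosome 11, MUC5AC and MUC5B had sites in DMSO lists only. Mucin genes were not tested as a group. MUC5AC had a DMSO-specific site of 10371 bases (1182155 to 1192525) with folds of 30.5 to 81.7, and MUC5B one of 10893 bases (1240851 to 1251743) with folds of 38.0 to 62.6. MUC6 had DMSO-specific sites at 1024844 to 1025083 and at 1031813 to 1032053, and its longest site (1015762 to 1018770) was in all 6 lists. The neighbouring genes AP2A2 and TOLLIP had sites in all 6 lists. MUC5AC and MUC5B are named under the rule fixed in advance, and MUC6, AP2A2 and TOLLIP were chosen after their values were seen.

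**Figure D4:**
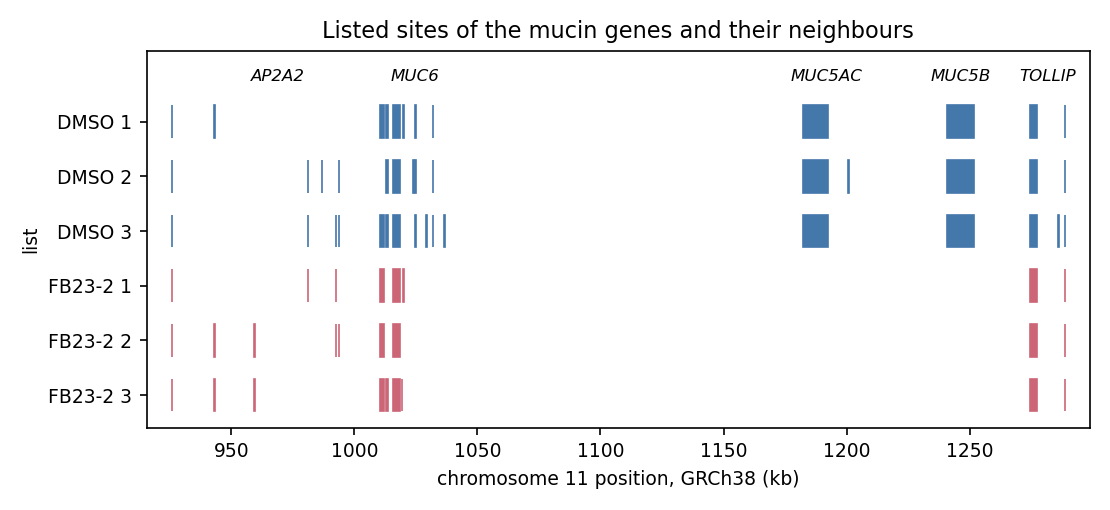
The horizontal axis is the position on chromosome 11 (GRCh38, kb) and each row is 1 of the 6 lists, with a bar for each listed site of AP2A2, MUC6, MUC5AC, MUC5B and TOLLIP. The DMSO-specific sites of MUC5AC and MUC5B appear in the 3 DMSO lists, a further MUC5AC site appears in DMSO replicate 2 only, and neither gene has a site in an FB23-2 list.

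The number of sites per gene also separated the treatments for some genes. It was higher in each FB23-2 list than in any DMSO list for 296 genes and lower for 466, together 7.54% of 10112 genes, where chance gives at most 10% with 3 against 3 and less for genes with tied numbers. The highest total of the other splits was 233 genes against 762. Sites were counted here as listed, before merging, so a broad peak called in pieces counts more than once. RNA levels may also change the number and were not analysed here, so gains and losses below are of listed sites. The largest gains with FB23-2 were in PER2, a core component of the circadian clock (13 ± 1.73 sites against 5 ± 1.00 with DMSO, SD, n = 3 each), CLIP2, a microtubule-binding protein (11 ± 1.00 against 4.67 ± 0.577), AHNAK2 (7.33 ± 1.53 against 1 in every list), SH2D3C (6 ± 1.73 against 0 in every list) and SESN2. AHNAK2 also carried a DMSO-specific site, so its only site in the DMSO lists was absent from every FB23-2 list. The largest losses were in LDB3 (1.33 ± 1.53 against 9 ± 1.00 with DMSO), TNC, the extracellular matrix protein tenascin-C (5 ± 2.00 against 12.7 ± 3.51), PLXNA2, a semaphorin receptor (5.33 ± 1.15 against 12 ± 2.65), DLG5, a scaffold protein of cell junctions (6 ± 2.65 against 12.7 ± 1.53), and SDK2, a cell adhesion protein (2.33 ± 0.577 against 8.67 ± 4.04).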

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

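The tests within classes of site number and on the best 50% against full lists were chosen after seeing the data. So were those on consecutive peak numbers and on neighbouring sites. The gene list tests with equal lists, other overlap or a list left out, and all alternative runs on separate site numbers, were chosen then too. Leaving out 1 list moved the difference in sites per list (FB23-2 minus DMSO) from -1318 to 95.5 and that in genes from -298.5 to 16.5, both turning only without DMSO replicate 3. It moved DMSO-specific sites to 826 to 1153, FB23-2-specific sites to 588 to 816 and genes with separate site numbers to 1038 to 1190, as fewer lists must then meet the rule. The difference of DMSO-specific and FB23-2-specific sites ran from 10 without FB23-2 replicate 3 to 557 without DMSO replicate 1. The number of gene list tests passing ranged from 1 to 3, with adjusted p of 0.0022 to 0.124 for axon guidance, 9.08e-04 to 0.0671 for ZNF genes and 9.08e-04 to 0.0077 for the stress response (Fisher's exact test). With the best 50% of each list, there were 370 DMSO-specific and 273 FB23-2-specific sites, a difference of 97, and 1 gene list test passed, with adjusted p of 0.0469 for the stress response, 0.611 for axon guidance and 0.301 for ZNF genes. With equal lists the difference was 88, and 1 list test passed (adjusted p of 4.27e-05 for the stress response and 0.104 for both others). Sites in the best 50% of every list of one treatment and absent from the full lists of the other numbered 76 for DMSO and 73 for FB23-2, a difference of 3. Group-specific sites with consecutive peak numbers numbered 278 for DMSO and 161 for FB23-2, a difference of 117. Without the 18 sites within 1000 bases of a site of opposite direction in the same gene, 659 DMSO-specific and 437 FB23-2-specific sites remained. Counting genes gave 209 and 118, a difference of 91. Axon guidance had an adjusted p of 0.0562 with 50% reciprocal overlap and 0.288 within classes of site number. ZNF genes had 0.352 with sites as units and 0.174 within classes, where 1 list test passed. The cause of these losses was not tested. The higher overlap within treatments kept its direction under all alternatives run (0.0423 to 0.0627). Of 43 named sites, 24 stayed group-specific in the best 50% and 42 in equal lists. The 10 strongest sites of each direction were named for their rank, so their staying in the best 50% was fixed by that choice. Of the other named sites, only those of YTHDF3, ATF3, CHAC1 and RPS24 stayed there. Same-numbered lists did not deviate together (correlations of 3.53e-04, 0.0277 and 0.0191), so the numbers do not pair them. With the replicate block the difference in sites stayed -691 (exact sign-flip p = 1, where 0.25 is the smallest possible) and that in genes -175 (exact p = 0.75). No block could change a presence in 3 of 3 against 0 of 3 lists. Without read counts, depth limits how far an unlisted site can be read as unmethylated.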

Other observations

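Among the terms annotated in the files, 4 of 3450 tests of a term in a direction passed the threshold, all for DMSO-specific sites. They were the extracellular region (41 of 294 genes, 13.9%, one-sided Fisher's exact test, adjusted p = 0.0093), homophilic cell adhesion (18 of 82 genes, 22.0%, adjusted p = 0.0093), calcium ion binding (37 of 282 genes, adjusted p = 0.0445) and the calcium signaling pathway (14 of 63 genes, adjusted p = 0.0445). The first held ADAMTS proteases and ANGPT2, the second many clustered protocadherins, and the last the ryanodine receptors RYR2 and RYR3 and the calcium channel genes CACNA1B, CACNA1D, CACNA1E and CACNA1H. The tests count genes as independent, which clustered protocadherins may not be, so the p of the second term may be too low. Within classes of genes with like numbers of sites, the first 2 had adjusted p of 0.0063 and 0.0217 and both calcium terms 0.101 (exact test). At an unadjusted p under 0.05 there were 169 tests, where chance gives at most 172.5. These terms, and the genes named here, were chosen after the data were seen.

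Of the tests in the following paragraphs, those on splits for separate numbers of sites and for the stress response genes, on the best 50% against full lists, on missing peak numbers, on the number of sites per gene, and on other sites of the stress response and mucin genes were chosen after the data were seen.

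The treatments differed in 1114 group-specific sites, and 1 of the 10 splits of the lists, the real one, gave that many, against 279 in the highest other. For genes with a site in 1 treatment only the values were 327 and 55, again with 1 of 10 splits, and for genes with separate numbers of sites 762 and 233, also with 1 of 10. With 10 splits no share under 0.05 is possible. The tables argue against unequal list length, since with equal lists the real total was 5.05 times the highest other split, and against weak sites near the threshold as the whole cause, since for sites in the best 50% against full lists it was 5.73 times (149 against 26). For the other 965 group-specific sites, weak signal near the threshold stays open, because the lists hold no signal below it. Missing peak numbers were not counted among the 149 sites, so weak signal and unlisted peaks acting together were not tested. Consecutive peak numbers in all 3 lists lacking them argue against peaks called but left out of the lists for 439 sites. A peak listed at a neighbouring interval would leave no number missing, so consecutive numbers do not show that no peak was called there. Peaks left out remain open for 379 sites with a missing number in all 3 lists and for 290 with one in 1 or 2. A missing number has no position. For 6 sites at a chromosome end of a list, the numbers cannot be read. A difference in RNA level stays open for all these counts, because input levels were not analysed here. Of the 1114 sites, 349 lay in 301 genes without any site in the lists of the other treatment.

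That 6 stress response genes had FB23-2-specific sites may reflect new methylation, more of their RNA or weak signal that crossed the caller's threshold. These cannot be told apart, because input levels were not analysed here and the lists hold no signal below the threshold. The mean rank percentiles of these sites within the FB23-2 lists ran from 15.8 (VLDLR) to 64.6 (ATF3). Of the 6 genes, 4 had another site in all 3 DMSO lists, so they were not without RNA there. The number of sites per gene does not account for it (exact p = 6.58e-05 within classes, in a test that counts genes as independent). Of their 11 FB23-2-specific sites, 0 had a missing peak number in all 3 DMSO lists. The real split gave 6 such genes and the highest other 1, with 1 of 10 splits as large, too few for a share under 0.05. A candidate explanation, not tested here, is that the compound induced a stress that raised these transcripts, which the inputs would show.

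Of the 4 DMSO-specific sites in MUC5AC, MUC5B and MUC6, 0 had a missing peak number in an FB23-2 list, which argues against peaks called but left out of the mRNA lists. Less RNA of these genes under FB23-2 stays open, since 1 of the 3 genes, MUC6, had any site there and input levels were not analysed here. Loss of methylation under an inhibitor of a demethylase would be the opposite of its direct effect, so a lower level of these transcripts is a hypothesis that the inputs could settle.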
